A study of Sus scrofa with 9 samples.

How the data were processed

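RNA was measured in longissimus dorsi muscle of embryonic pigs from 9 samples, 3 each of the Tibetan, Wujin and Large White breeds. Per the labels' protocols, the muscle was frozen on dry ice, RNA was taken up with Trizol, and libraries were built from 3 ug of total RNA with the TruSeq RNA kit; the series' design text names an Illumina HiSeq instrument. The authors deposited 1 table for the whole series that gives FPKM, fragment counts scaled by transcript length and library size, for each gene and sample, per the file headers. TopHat is named in the submitters' processing notes, with no version; the quantifier, the genome build and the annotation are not given in the sources used here. The table holds 19643 entries with 19597 distinct gene identifiers, and 84 entries have an identifier that occurs more than once. Gene symbols were matched by identifier from a table of gene names and were found for 11179 entries, or 56.91%, so many genes carry no name here. No reference genome was used, so no positions are given.

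Columns were assigned to samples by their headers. The Tibetan and Large White columns and Wujin 1 match a sample title. The 2 other Wujin columns share a header and were taken as replicates of the breed with no number of their own, called Wujin a and Wujin b; every column of sample values was used. FPKM are not counts, and the number of fragments behind each value is unknown, so no counting interval can be given. Relative depth was estimated from genes below 0.2 FPKM in both a library and Large White 1, where values move in steps worth 1 fragment. It was 1.22, 1.01 and 1.02 for Tibetan 1, 2 and 3, then 1.00, 1.08 and 1.14 for Wujin 1, a and b, and 1, 1.17 and 1.17 for Large White 1, 2 and 3. The 50 genes of highest mean FPKM are a large part of each total, and the 10 highest alone made up 32.5%, 26.6% and 38.6% of it in Tibetan 1, 2 and 3, but 20.5%, 20.4% and 21.0% in the Wujin and 16.9%, 23.1% and 15.6% in the Large White libraries. Among the tested genes, the median FPKM was 3.15 to 3.61 in Tibetan, 4.84 to 6.27 in Wujin and 6.72 to 7.20 in Large White libraries.

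Entries with a mean of at least 1 FPKM over all 9 samples were tested, 13106 of them, on the scale log2(FPKM + 1). Fold changes on this scale understate the change of genes with low values. limma 3.58.1 in R 4.3.3 fitted the 3 breed means to all 9 samples with 1 shared estimate of the spread (lmFit, contrasts.fit and eBayes with a trend on mean expression). It tested Tibetan minus Large White, Wujin minus Large White, Tibetan minus Wujin, the mean of Tibetan and Wujin minus Large White, and an F test of any difference among the breeds. P-values were adjusted by the Benjamini-Hochberg method over all entries tested, and a gene is called at an adjusted p under 0.05. Each tested gene's relative log2 change is its fitted change minus the median fitted change of all genes tested in that comparison.

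There were 33 gene lists for muscle, metabolism, growth signalling, stress and other cell types, and 22 key genes, of which 12 were matched by symbol. PAX7, MYOG, MYH7, MYH2, MYH1, MYH4, IGF2, MKI67, COL1A1 and FABP4 were not matched and may stand among the entries without a symbol. A list was tested with limma's camera, with a preset correlation between genes of 0.01, where at least 5 members passed the filter, which 29 lists did. Adjustment was over the lists of a comparison. The camera test compares a list with all other genes, so its direction follows the relative change. The skin and epithelium list with 4 measured members, the cardiac list with 2, the replication-dependent histones with 1 and the sex-linked list with 0 were not tested. Counts of called members are given over all genes tested and, where stated, adjusted over the list alone.

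The rule for genes named in the text took, for each pair of breeds, the 6 highest and 6 lowest fold changes among called genes with a symbol, a mean of at least 5 FPKM and no overlap between the replicate values of both breeds. It added the key genes, up to 4 members of smallest p in each list, and the 5 highest and 5 lowest genes called in the same direction in both comparisons with Large White. A gene with several entries was taken by the entry of highest mean FPKM. The text names a part of the genes that this rule gives, and that part was picked after their values were seen. The genes ACTA1, TNNC1, HBB, GAPDH, FOS, MX1, IRF9, OAS2, USP18, AHSG, TF and AFP and the entries without a symbol fall outside the rule and were chosen after their values were seen. The groups, tests, gene lists, naming rule and 26 of the alternative settings were chosen before the data were examined.

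The alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, and an added minimum of 1 on the absolute log2 fold change. Values were rescaled by median ratios over genes above 0 in every sample, by quantile normalization, to the same FPKM total, and to the same total without the 50 highest genes. The fit was repeated without the trend, with robust eBayes, with only the 6 libraries of the breeds compared, with the replicate number as a block, and without each library in turn. The lists were also tested with a correlation estimated for each list and with fry. A further 2 settings were added after seeing the data, one that set a 0 to missing where another library of the same breed had at least 100 FPKM, and one without Tibetan 2 and Wujin 1.

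The test code was first tested on simulated data with the 13106 tested entries, of which 200 were changed by known folds. The changed entries were drawn only from those with a mean log2(FPKM + 1) above 2, so recovery at lower levels was not measured. For Tibetan minus Large White it recovered 113 of the 200 with 5 unchanged ones called, or 17.9%, 61.2% and 90.9% of those changed by 1.5, 2 and 4 fold. For Wujin minus Large White it recovered 118 with 10 unchanged ones called, for Tibetan minus Wujin 121 with 9, and for the mean of both breeds 136 with 4. The F test recovered 111 with 7. A simulated shift of 1 list was called with none of the other lists. Since the simulated genes vary independently, this could not show false list calls that come from correlation between genes. Shared controls were modelled with 100 simulations of unchanged groups against a shared simulated Large White group. Noise was drawn independently for each gene and library. Other splits of the libraries into groups of the same sizes were counted, all 10 of them for each pair of breeds and 100 drawn with a fixed seed for the comparisons of 9 libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.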

Results

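RNA of the longissimus dorsi, the long muscle of the back, was sequenced from embryonic pigs of 3 breeds. The Tibetan and Wujin breeds are indigenous to China and Large White is an introduced breed, and each is represented by 3 libraries. The stated subject of the series is how muscle before birth relates to differences in growth after birth. The stage is given only as embryonic, with no gestational day. Of the 3 Wujin libraries, 1 carries the number 1 and the others share a header without distinct numbers, so they are called Wujin a and Wujin b here. The values are FPKM for 19643 gene entries, of which 13106 averaged at least 1 FPKM over the 9 libraries and were tested. Total FPKM was 615634, 590532 and 677783 in Tibetan 1, 2 and 3. It was 505042, 541368 and 550483 in Wujin 1, a and b, and 576076, 586937 and 541521 in Large White 1, 2 and 3. The number of reads behind these values is unknown, but the steps between low values place the depth of every library between 1 and 1.22 times that of Large White 1. Levels below are mean ± SD over n = 3 libraries. Nothing in the labels says that libraries of a breed came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

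The 3 Tibetan libraries stood apart from the other 6. Across genes, the Pearson correlation of log2(FPKM + 1) was 0.958 to 0.965 among Tibetan libraries, 0.941 to 0.966 among Wujin libraries and 0.957 to 0.968 among Large White libraries. Between breeds it was 0.890 to 0.955 for Wujin with Large White, 0.749 to 0.785 for Tibetan with Wujin and 0.697 to 0.742 for Tibetan with Large White. Genes are not independent replicates, so these coefficients only describe the libraries. The first principal component held 76.9% of the variance and separated Tibetan from both other breeds. The second held 8.77%, with Wujin 1 at its extreme, at -61.2 against -13.2 and -9.50 for Wujin a and b. limma's F test for any difference among the 3 breeds called 10173 of the 13106 genes at an adjusted p under 0.05.

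**Figure D1:**
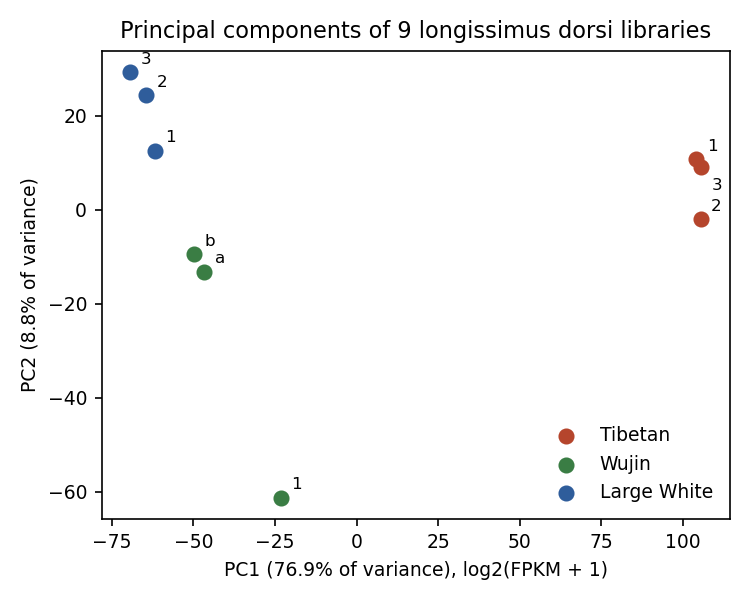
Scores of the 9 libraries on the first and second principal components of log2(FPKM + 1) over the 13106 genes tested, 1 point per library, with scores on the log2(FPKM + 1) scale on both axes and replicate names beside the points. The first component holds 76.9% of the variance and parts the 3 Tibetan libraries from the other 6, and Wujin 1 lies at -61.2 on the second.

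The comparison of Tibetan with Large White asks how prenatal muscle of a highland indigenous breed differs from that of a breed known for fast growth. Genes of the mature fast fibre were far higher in Tibetan muscle, and genes of the cell cycle and the extracellular matrix were lower, as were single genes of the embryonic sarcomere. With an estimated correlation none of these lists was called (adjusted p = 0.0803 for fast fibres, 0.307 for the cell cycle, 0.405 for the matrix and 0.405 for the embryonic sarcomere). MYBPC2, the fast-fibre myosin-binding protein C, stood at 1836 ± 490.5 FPKM in Tibetan against 2.48 ± 0.367 in Large White libraries. ACTC1, the cardiac alpha-actin that developing skeletal muscle also expresses, stood at 24.6 ± 4.73 against 6593 ± 659 FPKM. MYL4, the atrial and embryonic myosin light chain, stood at 3.72 ± 1.31 against 1657 ± 205 FPKM. The median log2 fold change over all genes tested was -0.77, so changes of single genes and lists in this comparison are given relative to that value, as relative log2 changes, with the standard error of the fitted fold change. The adjusted p-values test the fitted change, which lies 0.77 below the relative one.

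Among the 12 measured members of the fast-fibre sarcomere and calcium handling list, 11 rose in Tibetan muscle and 1 was not called. The list's median relative log2 change was 4.43 (limma's camera test, adjusted p = 3.76e-14; adjusted p = 0.0803 with an estimated correlation). The relative change was 9.78 ± 0.25 for MYBPC2, 6.55 ± 0.21 for ATP2A1, the calcium pump of fast fibres, and 4.88 ± 0.15 for MYOZ1, a protein of the Z-disc. Of the 22 members of the common sarcomere and membrane list, 14 rose, 2 fell and 6 were not called (median 2.02, adjusted p = 6.89e-12; adjusted p = 0.0803 with an estimated correlation). Under median-ratio scaling 12 fast-fibre and 19 common members were higher and 0 of either list lower. CKMT2, the mitochondrial creatine kinase of sarcomeric muscle, reached 708 ± 129.8 FPKM against 14.2 ± 1.71, and TCAP, the titin cap, had a relative change of 4.46 ± 0.19. Of the 8 slow-fibre members, 3 rose and 5 were not called (median 1.63, adjusted p = 0.00222; adjusted p = 0.396 with an estimated correlation), and after quantile normalization the list was no longer called (adjusted p = 0.0755). Under median-ratio scaling 6 slow-fibre members were higher and 0 lower. Tibetan 2 lay apart, with a list median of 2.34 against 0.93 and 1.08 in Tibetan 1 and 3, and without it the adjusted p was 0.0443. TNNC1, slow troponin C, stood at 8645 FPKM there against 1663 and 1615. PPARGC1A, a coactivator of mitochondrial gene expression, changed by 3.85 ± 0.36. MYH6, a cardiac myosin heavy chain that shares near-identical sequence with MYH7 so that its reads cannot be assigned with certainty, changed by 1.92 ± 0.20. TNNT1, slow troponin T, stood at 893, 2855 and 1044 FPKM in Tibetan 1, 2 and 3. Its fitted change of 1.01 ± 0.41 was no longer called with equal totals (0.87), with no filter, the replicate block or only the 6 libraries (all 1.01), without Tibetan 2 (0.49), without any single Wujin library (1.01), or without Large White 1, 2 or 3 (1.18, 0.93 and 0.92). Adjusted over the list alone, 11 fast-fibre, 14 common and 2 slow-fibre members were higher.

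Of the 9 members of the embryonic and neonatal sarcomere list, 6 fell, 1 rose and 2 were not called. The median relative change was -3.10, yet the list as a whole was not called (adjusted p = 0.217; adjusted p = 0.405 with an estimated correlation), and it was called after median-ratio scaling (adjusted p = 0.0289) and after quantile normalization (adjusted p = 0.00976). Under median-ratio scaling 6 members were lower and 2 higher. MYH3, the embryonic myosin heavy chain, fell from 1754 ± 208 FPKM in Large White to 62.6 ± 8.70 in Tibetan libraries (relative change -4.02 ± 0.16, adjusted p = 5.87e-08). TNNT2, cardiac and embryonic troponin T, changed by -5.29 ± 0.20. MYH8, the perinatal myosin heavy chain, went the other way, from 54.0 ± 4.75 to 3330.4 ± 512 FPKM (6.68 ± 0.14). The skeletal myosin heavy chains lie in a cluster of similar genes, so their levels carry that uncertainty. Of 20 myogenic regulators, 15 fell, 2 rose and 3 were not called, with a median of -0.81 (adjusted p = 0.145; adjusted p = 0.417 with an estimated correlation). The list passed the test after quantile normalization (adjusted p = 0.0347), and under median-ratio scaling 12 were lower and 5 higher. MYF5, an early determination factor, fell from 46.9 ± 3.51 to 4.68 ± 1.49 FPKM (relative change -2.34 ± 0.20, adjusted p = 1.10e-06). MYMK, which drives fusion of myoblasts, changed by -3.54 ± 0.25. MSTN, the inhibitor of muscle growth, stood at 2.35 ± 1.92 FPKM against 30.2 ± 3.12 (-2.63 ± 0.45, adjusted p = 0.000110), and its antagonist FST at 3.39 ± 1.28 against 20.8 ± 1.21 (-1.58 ± 0.20). MYOD1 was called lower with a fitted change of -0.89 ± 0.14, which is -0.12 relative to all genes, and its sign turned to 0.060 under median-ratio scaling. MYF6 was called higher with a fitted change of 0.60 ± 0.22 (adjusted p = 0.0317), a call that ended without Tibetan 2 (0.63), Tibetan 3 (0.34), Large White 2 (0.55) or Large White 3 (0.60), with equal totals (0.46), and with the replicate block or only the 6 libraries (both 0.60). PAX3, a factor of muscle progenitors, stayed below the expression filter in every breed, with 0.159 FPKM in Tibetan 3 as its highest value.

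**Figure D2:**
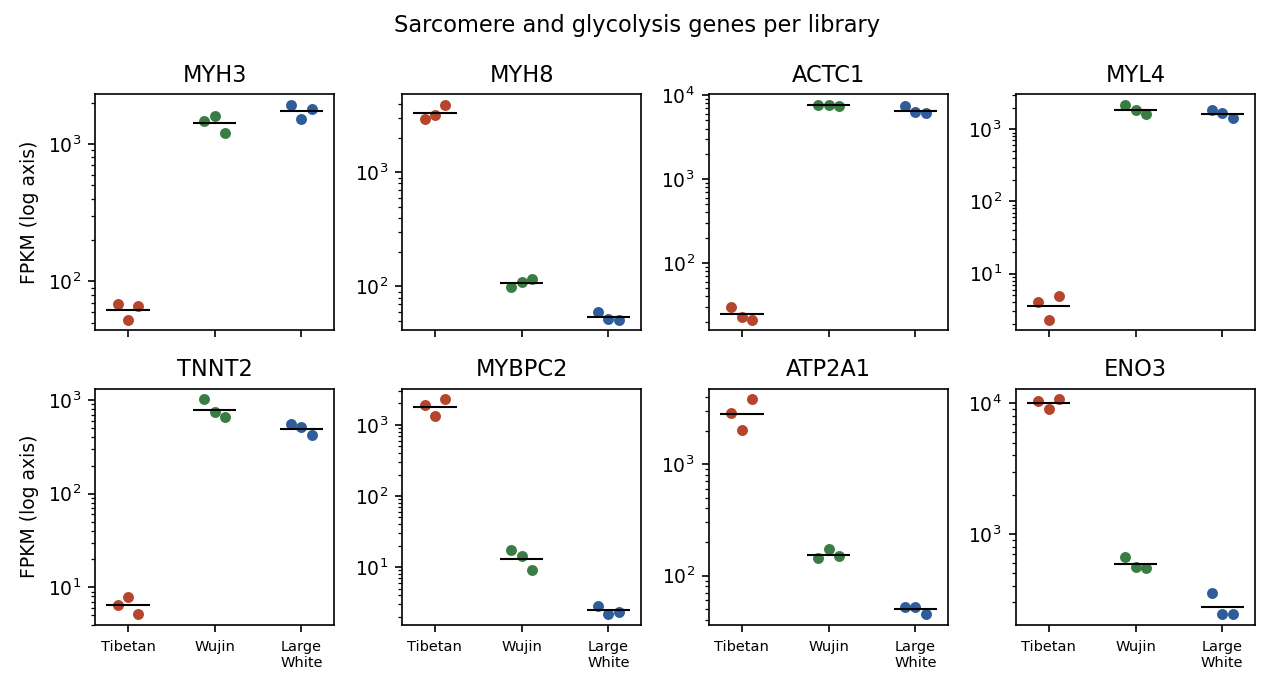
FPKM on a log axis of 8 muscle genes in each of the 9 libraries by breed; points are libraries and black lines geometric means. MYH3, ACTC1, MYL4 and TNNT2 are lowest and MYH8, MYBPC2, ATP2A1 and ENO3 highest in Tibetan muscle, as for MYBPC2 with means of 1836 FPKM in Tibetan, 13.5 in Wujin and 2.48 in Large White libraries.

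Genes of energy metabolism were higher in Tibetan muscle relative to all genes, though no list was called with an estimated correlation. Of 34 measured members of the glycolysis and glycogen list, 23 rose, 5 fell and 6 were not called (median 3.16, adjusted p = 6.35e-17; adjusted p = 0.0834 with an estimated correlation). ENO3, muscle enolase, reached 10072 ± 933 FPKM against 281 ± 63.5, and PYGM, muscle glycogen phosphorylase, changed by 6.11 ± 0.20. SLC2A4, the insulin-responsive glucose transporter, changed by 6.78 ± 0.16 and FBP2, muscle fructose bisphosphatase, by 8.35 ± 0.24. Of 42 nuclear genes of oxidative phosphorylation, 38 rose, 2 fell and 2 were not called (median 2.13, adjusted p = 3.78e-27; adjusted p = 0.0803 with an estimated correlation). SDHB, a subunit of succinate dehydrogenase, reached 247 ± 2.81 FPKM against 47.9 ± 0.872, and COX5A, a subunit of cytochrome oxidase, 518 ± 49.6 against 107 ± 5.32. Of 20 genes of the tricarboxylic acid cycle, 17 rose, 1 fell and 2 were not called (median 2.11, adjusted p = 2.32e-15; adjusted p = 0.0803 with an estimated correlation), with IDH2, mitochondrial isocitrate dehydrogenase, at 3.24 ± 0.12. Of 28 genes of fatty acid oxidation, 18 rose, 4 fell and 6 were not called (median 1.77, adjusted p = 5.73e-12; adjusted p = 0.0803 with an estimated correlation). PDK4, which restrains glucose oxidation, changed by 5.49 ± 0.36 and ACADVL, the very long chain acyl-CoA dehydrogenase, by 3.17 ± 0.14. Of 13 genes of the mitochondrial genome, 6 rose, 2 fell and 5 were not called (median 1.19, adjusted p = 0.000246; adjusted p = 0.417 with an estimated correlation), but after quantile normalization the list's direction turned and it was not called (adjusted p = 0.953), while under median-ratio scaling 11 were higher and 0 lower. COX1 had a relative change of 1.54 ± 0.13 and a fitted value of -0.061 after quantile normalization, and ND2 was called lower with a fitted change of -1.10 ± 0.24, which is -0.33 relative to all genes, and was not called under median-ratio scaling (fitted change -0.13). The adipogenesis and lipid storage list had 6 members higher, 8 lower and 4 not called, or 7 higher and 6 lower under median-ratio scaling. Its median relative change was 0.55 (adjusted p = 0.0422; adjusted p = 0.396 with an estimated correlation). PLIN4, which coats lipid droplets, and PNPLA2, which begins the breakdown of triglycerides, changed by 4.79 ± 0.19 and 4.30 ± 0.16, and FADS1, a fatty acid desaturase, by -1.69 ± 0.14. That list was no longer called without Tibetan 2 (adjusted p = 0.0705), Tibetan 3 (0.0616), Wujin 1 (0.0582) or Large White 1 (0.0539), nor after median-ratio scaling (0.375) or quantile normalization (0.285), with at least 5 FPKM (0.298), a pseudocount of 5 (0.0530), equal totals without the 50 highest genes (0.0811), only the 6 libraries (0.0561) or the replicate block (0.0622). Adjusted over the list alone, 23 glycolysis, 38 oxidative phosphorylation, 17 tricarboxylic acid cycle and 18 fatty acid oxidation genes were higher. Under median-ratio scaling 27, 40, 19 and 24 were higher and 4, 0, 0 and 1 lower.

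All 33 measured members of the cell cycle list fell in Tibetan muscle, also when adjusted over the list alone (median -1.81, adjusted p = 2.84e-08; adjusted p = 0.307 with an estimated correlation), and 32 of them were called lower under median-ratio scaling. UBE2C, which acts at the exit from mitosis, fell from 35.2 ± 1.57 to 0.578 ± 0.166 FPKM, and MCM2, a subunit of the replicative helicase, from 21.4 ± 0.716 to 0.303 ± 0.0909. Of 24 ribosomal proteins, 22 fell and 2 were not called (median -0.45, adjusted p = 0.0289; adjusted p = 0.603 with an estimated correlation), but under median-ratio scaling only 4 were called lower and 2 higher. RPS4X and RPL5 changed by -0.93 ± 0.11 and -0.67 ± 0.12, and the list was no longer called without Wujin 1 (adjusted p = 0.0720), after median-ratio scaling, with equal totals (0.0674), with only the 6 libraries (0.0866) or with the replicate block (0.0622). Of 32 growth factor and insulin-like growth factor signalling genes, 7 rose, 17 fell and 8 were not called, against 14 higher and 9 lower under median-ratio scaling. The median relative change was 0.18 while the fitted median and mean were both -0.59 (adjusted p = 0.204; adjusted p = 0.642 with an estimated correlation). FGFR4, a fibroblast growth factor receptor, changed by -3.37 ± 0.12 and GRB10, an adaptor that restrains insulin signalling, by 2.26 ± 0.14. IGF1 stood at 3.93 ± 0.976 FPKM against 17.0 ± 6.29 (-1.06 ± 0.32, adjusted p = 0.000648). Its receptor IGF1R stood at 0.456 ± 0.173 FPKM against 1.98 ± 0.281, low levels at which log2(FPKM + 1) understates changes. The relative change of IGF1R was -0.27 ± 0.17, and it was not called after quantile normalization (fitted change -0.28). Of 32 TGF-beta and BMP signalling genes, 27 fell and 5 were not called (median -0.61, adjusted p = 0.0198; adjusted p = 0.480 with an estimated correlation), with TGFB3, a ligand of the pathway, at -2.16 ± 0.17 and LTBP3, which binds latent TGF-beta, at -1.97 ± 0.12. Under median-ratio scaling 19 of these were lower and 5 higher. Of 25 Wnt signalling genes, 20 fell, 1 rose and 4 were not called, and the list was not called (median -0.51, adjusted p = 0.0612; adjusted p = 0.450 with an estimated correlation). It was called without Tibetan 1 (adjusted p = 0.0483) or Large White 3 (0.0438), after median-ratio scaling (0.0471) or quantile normalization (0.0423) and with no filter (0.0172). Under median-ratio scaling 13 members were lower and 2 higher. SFRP2 and DKK3, both secreted modulators of Wnt signalling, changed by -5.44 ± 0.16 and -2.84 ± 0.13. Of 15 imprinted genes, 14 fell and 1 rose (median -0.86, adjusted p = 0.0334; adjusted p = 0.336 with an estimated correlation), with MEST, expressed from the paternal allele, at -4.45 ± 0.19. Their call ended with a pseudocount of 5 (adjusted p = 0.0512) or at least 5 FPKM (0.0694), and under median-ratio scaling 11 were lower and 1 higher. Of 15 genes linked to growth and carcass traits of pigs, 8 fell, 3 rose and 4 were not called, against 6 lower and 6 higher under median-ratio scaling. The median relative change was 0.16 against a fitted median of -0.61 (adjusted p = 0.338; adjusted p = 0.642 with an estimated correlation), and PHKG1, a catalytic subunit of phosphorylase kinase, changed by 3.10 ± 0.25.

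Genes of connective tissue were lower in Tibetan muscle, though no list was called with an estimated correlation. Of 43 extracellular matrix genes, 42 fell and 1 was not called, also when adjusted over the list alone (median -2.49, adjusted p = 1.60e-07; adjusted p = 0.405 with an estimated correlation). Under median-ratio scaling 38 were lower and 1 higher. COL1A2, a chain of fibrillar collagen, fell from 1415 ± 69.9 to 48.8 ± 7.15 FPKM, and VCAN, a large proteoglycan, changed by -5.10 ± 0.16. POSTN, a matrix protein of the same list, fell from 393 ± 108 to 1.36 ± 0.136 FPKM. All 9 cartilage, bone and tendon genes fell (median -2.24, adjusted p = 0.0346; adjusted p = 0.436 with an estimated correlation), with TNMD, a tendon marker, at -4.84 ± 0.45 and COL11A1, a cartilage collagen, at -4.19 ± 0.30. That list was no longer called without Wujin 1 (adjusted p = 0.0698), with no filter (0.130), at least 5 FPKM (0.0694), a pseudocount of 5 (0.0782), equal totals (0.0549), only the 6 libraries (0.0706) or the replicate block (0.0622). Under median-ratio scaling 8 of the 9 genes were lower. Of 21 endothelial and mural genes, 10 fell, 2 rose and 9 were not called, against 5 lower and 10 higher under median-ratio scaling. Their median relative change was 0.34, against a fitted median of -0.43 (adjusted p = 0.300; adjusted p = 0.664 with an estimated correlation). ACTA2, smooth muscle actin, and NOTCH3, a receptor of mural cells, changed by -2.16 ± 0.18 and -1.82 ± 0.16. Of 8 neural and Schwann cell genes, 6 fell, 1 rose and 1 was not called (median -1.18, adjusted p = 0.217; adjusted p = 0.405 with an estimated correlation), with the neuregulin receptor ERBB3 at -3.94 ± 0.12. This list was called after median-ratio scaling (adjusted p = 0.0418), with 6 lower and 2 higher. Of 8 haemoglobin and erythroid genes, 4 fell, 2 rose and 2 were not called, against 3 lower and 4 higher under median-ratio scaling. The median relative change was 0.19, against a fitted median of -0.58 (adjusted p = 0.217; adjusted p = 0.534 with an estimated correlation). ALAS2, of haem synthesis in red cells, changed by -1.72 ± 0.33, and TFRC, the transferrin receptor, by 2.41 ± 0.21. Of 17 macrophage and immune genes, 3 rose, 5 fell and 9 were not called, against 10 higher and 2 lower under median-ratio scaling. Relative to all genes the median was 0.77, against a fitted median of 0.00 and a fitted mean of -0.12 (adjusted p = 0.0166; adjusted p = 0.450 with an estimated correlation), and the list was no longer called without Tibetan 2 (adjusted p = 0.0603) or after median-ratio scaling (0.0789). CX3CR1, the fractalkine receptor, changed by -0.92 ± 0.21 and SLA-DQB1, an MHC class II chain, by 3.18 ± 0.17. CX3CR1 stood at 0.101 ± 0.0445 FPKM in Tibetan against 2.59 ± 0.573 in Large White libraries, low levels at which log2(FPKM + 1) understates changes. Of 22 MHC class I and interferon response genes, 8 rose, 2 fell and 12 were not called (median 1.53, adjusted p = 1.31e-05; adjusted p = 0.396 with an estimated correlation), with IRF1 at 1.97 ± 0.27 and STAT2 at -0.68 ± 0.17. The list was not called with at least 5 FPKM (adjusted p = 0.0675), and under median-ratio scaling 14 were higher and 1 lower. The pig MHC genes are a family of near-identical copies. Of 10 liver and visceral genes, 3 fell and 7 were not called, against 2 lower under median-ratio scaling. Their median relative change was 0.33, against a fitted median of -0.45 (adjusted p = 0.294; adjusted p = 0.664 with an estimated correlation), and the list was called without Tibetan 3 (adjusted p = 0.0397). APOA1, the main apolipoprotein of high-density lipoprotein, changed by -1.68 ± 0.16.

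Of 31 immediate early and stress genes, 17 rose, 7 fell and 7 were not called (median 1.68, adjusted p = 2.35e-08; adjusted p = 0.0890 with an estimated correlation). Under median-ratio scaling 25 were higher and 3 lower. HSPA1L, a heat shock protein whose family holds near-identical copies, reached 735, 1765 and 835 FPKM in Tibetan 1, 2 and 3 against 39.9 ± 6.33 in Large White libraries, and ZFP36, an RNA-binding protein of the early response, changed by 4.15 ± 0.20. Of 26 genes of the proteasome and muscle protein breakdown, 13 rose, 5 fell and 8 were not called (median 1.10, adjusted p = 1.60e-07; adjusted p = 0.243 with an estimated correlation). Under median-ratio scaling 23 were higher and 0 lower. The muscle ubiquitin ligases TRIM63 and FBXO32 changed by 4.24 ± 0.18 and 3.74 ± 0.36. Of 25 hypoxia response genes, 7 rose, 13 fell and 5 were not called, against 13 higher and 6 lower under median-ratio scaling. Relative to all genes the median was 0.35, against a fitted median of -0.42 and a fitted mean of 0.03 (adjusted p = 0.0303; adjusted p = 0.480 with an estimated correlation), and the list was no longer called without Wujin 1 (adjusted p = 0.0573). Its call also ended after median-ratio scaling (0.115) or quantile normalization (0.142), with at least 5 FPKM (0.0699), no filter (0.0721), equal totals without the 50 highest genes (0.0502) or only the 6 libraries (0.0561). LDHA, lactate dehydrogenase A, and VEGFA, the vascular growth factor, changed by 4.51 ± 0.18 and 3.90 ± 0.28, and BNIP3L, of mitophagy, by -1.51 ± 0.14. EPAS1, the hypoxia-inducible factor whose variants mark highland populations, changed by 1.65 ± 0.19 (adjusted p = 0.00217), from 10.3 ± 0.276 to 20.0 ± 5.04 FPKM.

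limma called 9983 of the 13106 genes between Tibetan and Large White, 1703 higher and 8280 lower in Tibetan muscle, and 6149 of these had a fold change of at least 2. The camera test called 20 of 29 lists, 14 up and 6 down, and fry called 21. With an estimated correlation for each list, camera called 0, and 7 had an unadjusted p under 0.05. The balance of directions depended on scaling. Median-ratio scaling gave 8572 genes, 4245 higher and 4327 lower, of which 6030 were called in the same direction as before and 407 in the opposite one. Quantile normalization gave 4035 higher and 4352 lower.

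The comparison of Wujin with Large White sets the other indigenous breed against the same introduced breed. It gave far fewer changes, with 6 of 12 fast-fibre genes higher and 10 of 33 cell cycle genes lower in Wujin muscle. Under median-ratio scaling these were 5 and 2, and neither list was called with an estimated correlation (adjusted p = 0.704 and 0.852). FBP2 stood at 11.9 ± 1.10 FPKM in Wujin against 0.675 ± 0.115 in Large White libraries, and MYBPC2 at 13.5 ± 4.14 against 2.48 ± 0.367. KIT, the receptor of stem cell factor at the locus that sets white coat colour in pigs, stood at 3.09 ± 0.989 against 24.4 ± 0.528 FPKM. HCLS1, a signalling protein of blood cells, stood at 3.03 ± 0.261 against 48.3 ± 4.18 FPKM. The median over all genes was -0.20, and changes are again given relative to it.

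Among genes called under every alternative setting that gave them a value, the relative change was 3.14 ± 0.24 for FBP2 (adjusted p = 0.000762), 2.22 ± 0.25 for MYBPC2 (adjusted p = 0.00668) and 1.80 ± 0.21 for ATP2A1 (adjusted p = 0.00753). ART3, of the ADP-ribosyltransferase family, changed by 2.91 ± 0.29 and the phosphatase DUSP26 by 2.27 ± 0.24. On the lower side it was -3.41 ± 0.14 for HCLS1 (adjusted p = 1.28e-05) and -2.47 ± 0.19 for KIT (adjusted p = 0.000330). DCX, a microtubule-binding protein of young neurons, changed by -2.52 ± 0.20 and EPHA3, an ephrin receptor, by -2.39 ± 0.20. CORT, which encodes the neuropeptide cortistatin, was listed at 0, 2.45 and 0 FPKM in Wujin 1, a and b and at 6.27, 31.7 and 46.6 in Large White 1, 2 and 3. Its call ended without Wujin 1, Large White 2 or Large White 3 (fitted changes -3.60, -3.62 and -3.35) and with only the 6 libraries (-3.89). MYH8 stood at 108 ± 8.83 FPKM in Wujin against 54.0 ± 4.75 (1.19 ± 0.14, adjusted p = 0.0109), and its fitted change of 0.99 was no longer called without Large White 2 (0.96) or Large White 3 (0.95). The other 10 key genes of muscle growth that were tested were not called. MSTN stood at 16.1 ± 6.72 against 30.2 ± 3.12 FPKM (-0.76 ± 0.45, adjusted p = 0.178), IGF1 at 9.53 ± 3.65 against 17.0 ± 6.29 (-0.59 ± 0.32, adjusted p = 0.133) and MYH3 at 1429 ± 208 against 1754 ± 208 (-0.10 ± 0.16, adjusted p = 0.230). The adjusted p was 0.804 for FST, 0.734 for MYF5, 0.403 for MYOD1 and 0.127 for MYF6, and 0.241 for IGF1R, 0.862 for PPARGC1A and 0.834 for EPAS1.

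Of the 12 fast-fibre members, 6 rose and 6 were not called, 9 higher when adjusted over the list alone (median 0.98, adjusted p = 1.41e-09; adjusted p = 0.704 with an estimated correlation). Of the 22 common sarcomere members, 1 rose, 2 fell and 19 were not called (median 0.39, adjusted p = 0.000661; adjusted p = 0.852 with an estimated correlation). Of the 33 cell cycle members, 10 fell and 23 were not called, 22 lower when adjusted over the list alone (median -0.26, adjusted p = 0.000379; adjusted p = 0.852 with an estimated correlation), but 2 were lower under median-ratio scaling. Of the 34 glycolysis members, 3 rose, 1 fell and 30 were not called (median 0.29, adjusted p = 0.000661; adjusted p = 0.852 with an estimated correlation). Of the 13 mitochondrial genome members, 4 fell and 9 were not called (median -0.33, adjusted p = 0.00786; adjusted p = 0.967 with an estimated correlation). ND2 and ND6, subunits of complex I, changed by -2.08 ± 0.24 and -1.21 ± 0.18. The list was no longer called without Wujin 1 (adjusted p = 0.0661). None of the 22 MHC class I and interferon response members was called, while the list was (median 0.62, adjusted p = 0.000265; adjusted p = 0.852 with an estimated correlation). That list call rested on Wujin 1, in which 20 of the 22 members were higher than in the mean of the other Wujin libraries, and it ended without that library (adjusted p = 0.277) and with at least 5 FPKM (0.219). Of the 42 nuclear oxidative phosphorylation members, 1 rose, 1 fell and 40 were not called (median 0.23, adjusted p = 0.00919; adjusted p = 0.852 with an estimated correlation), a list call that ended without Wujin 1 (adjusted p = 0.130) or Large White 3 (0.105), after quantile normalization (0.230) and with at least 5 FPKM (0.0993). Of the 21 endothelial and mural members, 1 rose and 20 were not called (median 0.23, adjusted p = 0.0203; adjusted p = 0.852 with an estimated correlation), which ended without Wujin b (adjusted p = 0.0587) or Large White 3 (0.0513), with no filter (0.167) and with at least 5 FPKM. Of the lists not called, the extracellular matrix list was called after quantile normalization (camera, adjusted p = 0.00289) and without Wujin b (0.0108). The liver and visceral list was called without Large White 1 (adjusted p = 0.00287), with only the 6 libraries (0.0332) and after quantile normalization (0.0438). The embryonic and neonatal sarcomere list was called without Large White 1 (adjusted p = 0.0469). Under median-ratio scaling 5 fast-fibre, 1 common sarcomere, 4 glycolysis and 1 endothelial members were higher, and 1 glycolysis and 3 mitochondrial genome members lower.

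**Figure D3:**
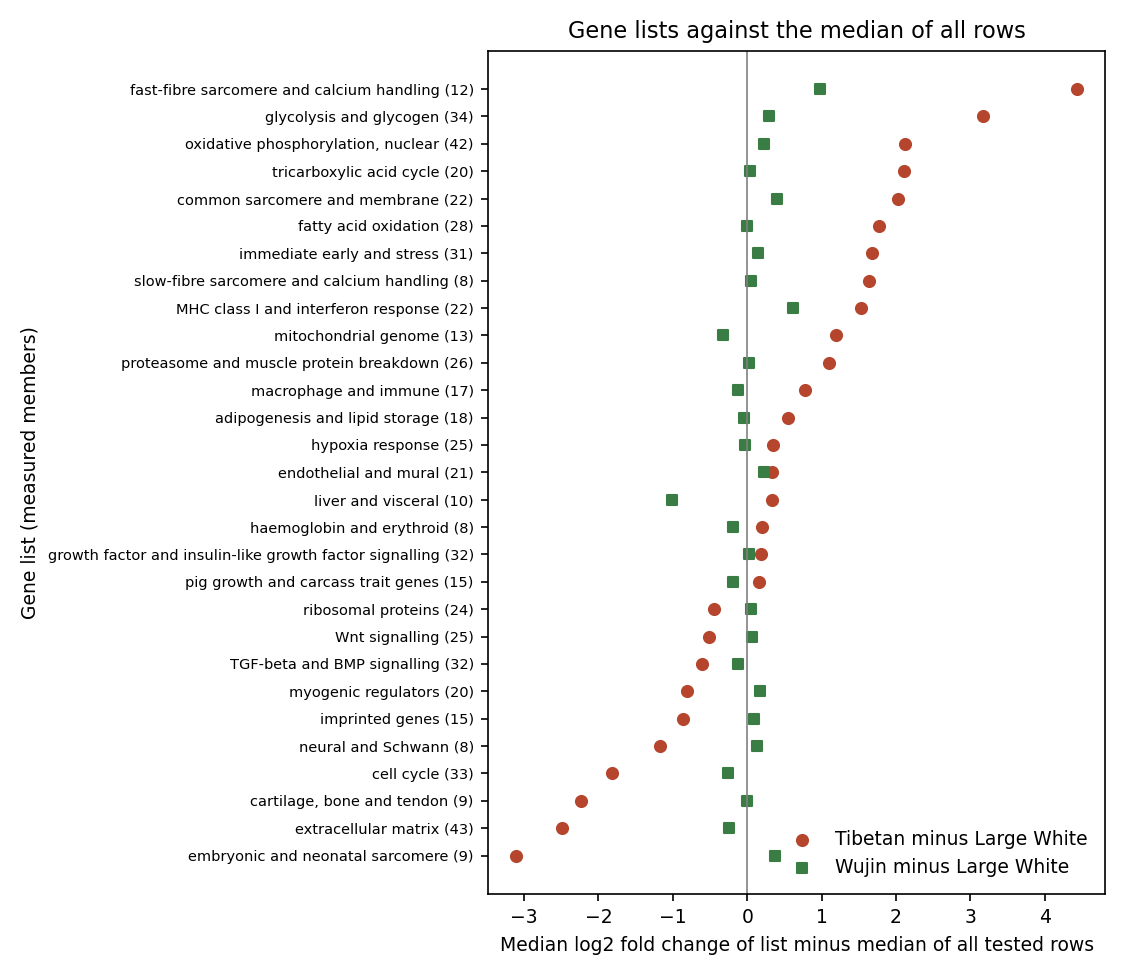
Median log2 fold change of each tested gene list minus the median of all genes tested, in log2 units, with circles for Tibetan minus Large White and squares for Wujin minus Large White. The fast-fibre list lies at 4.43 and 0.98 and the extracellular matrix list at -2.49 and -0.24, and after quantile normalization the mitochondrial genome list of Tibetan minus Large White changed direction.

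limma called 855 genes between Wujin and Large White, 219 higher and 636 lower, and 227 of them had a fold change of at least 2. The camera test called 8 of 29 lists, 6 up and 2 down, and 5 without Wujin 1, while fry called 3. With an estimated correlation camera called 0, and 1 had an unadjusted p under 0.05. The number of genes was 412 under median-ratio scaling (245 higher and 167 lower), 850 after quantile normalization (470 and 380), 608 with equal totals (267 and 341) and 453 with equal totals without the 50 highest genes (239 and 214). It was 390 without Tibetan 1, 409 without Tibetan 3, 430 without Wujin 1, 141 without Wujin a, 1633 without Wujin b, and 184, 88 and 66 without Large White 1, 2 and 3.

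The comparison of Tibetan with Wujin sets both indigenous breeds against each other, with fast-fibre genes again higher in Tibetan muscle and ACTC1, MYL4 and MYH3 again lower. The fast-fibre list was not called with an estimated correlation (adjusted p = 0.0920). MYBPC2 was at 1836 ± 490.5 FPKM in Tibetan against 13.5 ± 4.14 in Wujin libraries, and CKMT2 at 708 ± 129.8 against 7.74 ± 2.10. ACTC1 was at 24.6 ± 4.73 against 7582 ± 199 FPKM, and NES, the intermediate filament nestin of progenitor cells, at 5.73 ± 2.14 against 359 ± 80.2. The median over all genes was -0.55, and changes are given relative to it. The relative change was 7.54 ± 0.25 for MYBPC2 (adjusted p = 8.72e-08), 6.90 ± 0.20 for CKMT2, 6.62 ± 0.24 for ANKRD23, a muscle ankyrin repeat protein, and 5.47 ± 0.14 for MYH8. It was -8.12 ± 0.22 for MYL4 and -7.68 ± 0.15 for ACTC1 (adjusted p = 6.29e-09).

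Of the 12 fast-fibre members, 11 rose and 1 was not called (median 3.57, adjusted p = 8.04e-12; adjusted p = 0.0920 with an estimated correlation). Of the 9 embryonic and neonatal sarcomere members, 6 fell, 1 rose and 2 were not called, and the list was not called (median -2.34, adjusted p = 0.0933; adjusted p = 0.247 with an estimated correlation). It was called after median-ratio scaling (adjusted p = 0.0163) or quantile normalization (0.00666), with no filter (0.0421) and without Tibetan 2 (0.0298). All 33 cell cycle members fell (median -1.43, adjusted p = 8.50e-09; adjusted p = 0.245 with an estimated correlation), as did all 43 extracellular matrix members (median -2.20, adjusted p = 1.61e-08; adjusted p = 0.333 with an estimated correlation). Of the 42 nuclear oxidative phosphorylation members, 36 rose, 2 fell and 4 were not called (median 1.79, adjusted p = 3.22e-23; adjusted p = 0.0751 with an estimated correlation). Of the 34 glycolysis members, 24 rose, 5 fell and 5 were not called (median 2.58, adjusted p = 4.43e-15; adjusted p = 0.0920 with an estimated correlation). Of the 13 mitochondrial genome members, 12 rose and 1 was not called (median 1.48, adjusted p = 1.53e-08; adjusted p = 0.245 with an estimated correlation). Adjusted over the list alone, 11 fast-fibre, 36 oxidative phosphorylation, 25 glycolysis and 13 mitochondrial genome members were higher. Under median-ratio scaling 11, 39, 28 and 13 were higher and 0, 0, 3 and 0 lower, and 31 cell cycle and 36 extracellular matrix members were lower. MYF5 had a relative change of -2.67 ± 0.20, MSTN of -1.90 ± 0.45 (adjusted p = 0.00107), FST of -1.72 ± 0.20 and MYH3 of -3.94 ± 0.16. PPARGC1A changed by 3.53 ± 0.36 and EPAS1 by 1.49 ± 0.19 (adjusted p = 0.00174). MYOD1 and IGF1R had values of -0.52 ± 0.14 and -0.19 ± 0.17, and their calls ended under median-ratio scaling and quantile normalization, respectively. IGF1R stood at 0.456 ± 0.173 FPKM in Tibetan against 1.45 ± 0.396 in Wujin libraries, where log2(FPKM + 1) understates changes. IGF1 had a fitted change of -1.05 ± 0.32 (adjusted p = 0.0169) that was not called without Tibetan 1 (-0.88), Wujin a (-0.91) or Wujin b (-0.86). It shrank to -0.42 under median-ratio scaling and -0.46 after quantile normalization, and neither was called. MYF6 was not called (fitted change 0.05 ± 0.22, adjusted p = 0.845) but was under median-ratio scaling (0.78).

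limma called 8871 genes between Tibetan and Wujin, 1809 higher and 7062 lower in Tibetan muscle. Median-ratio scaling gave 4052 higher and 3978 lower, with 5787 called in the same direction as before, and quantile normalization gave 3766 and 4159. The camera test called 22 of 29 lists, 14 up and 8 down, and fry called 23. With an estimated correlation camera called 0, and 8 had an unadjusted p under 0.05.

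The mean of both indigenous breeds was then compared with Large White, to find genes that set the introduced breed apart from both. Genes called in the same direction in both breeds included FBP2, ART3, DUSP26, MYBPC2 and PEBP4, which were higher, and HCLS1, DCX, KIT and EPHA3, which were lower. HCLS1 stood at 2.69 ± 0.641 FPKM in Tibetan, 3.03 ± 0.261 in Wujin and 48.3 ± 4.18 in Large White libraries. KIT stood at 0.313 ± 0.144, 3.09 ± 0.989 and 24.4 ± 0.528 FPKM, and PEBP4 at 134 ± 24.4, 27.4 ± 4.43 and 8.07 ± 1.11. Relative to the median of -0.49 over all genes, the change of the mean was 5.75 ± 0.21 for FBP2 (adjusted p = 7.44e-07), 4.28 ± 0.25 for ART3 and 3.26 ± 0.15 for PEBP4. It was -3.19 ± 0.12 for HCLS1 (adjusted p = 6.23e-07), -2.98 ± 0.16 for KIT and -2.80 ± 0.17 for EPHA3. CORT was listed at 0 in all 3 Tibetan libraries. The fast-fibre list had 11 of 12 members higher (median 2.49, adjusted p = 9.50e-16; adjusted p = 0.0768 with an estimated correlation) and the cell cycle list all 33 lower (median -0.86, adjusted p = 2.33e-09; adjusted p = 0.279 with an estimated correlation). These counts rest mainly on Tibetan muscle, as 6 of 12 and 10 of 33 were called in Wujin, or 5 and 2 under median-ratio scaling.

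limma called 8643 genes in this comparison, 1298 higher and 7345 lower. Median-ratio scaling gave 3313 higher and 3336 lower and quantile normalization 3123 and 3400. The calls of Tibetan and of Wujin against Large White shared 693 genes in the same direction, 120 higher and 573 lower. Unchanged groups simulated against a shared Large White group had a median of 0 and at most 1 in common. Groups without any change give almost no calls after adjustment, so these counts could not show how many shared calls the shared controls add. Independent lists of these sizes would share 28.5 higher and 402 lower. A further 79 genes were called in opposite directions, where independent lists would give 221. The simulations gave 0, which for the same reason is no baseline. The shared number was 319 without Tibetan 1, 330 without Tibetan 3, 361 without Wujin 1, 121 without Wujin a and 1366 without Wujin b. It was 156, 74 and 54 without Large White 1, 2 and 3, 292 under median-ratio scaling and 214 with a pseudocount of 0.1. Across genes, the fold changes of both comparisons had a Pearson correlation of 0.419, below the simulated median of 0.501. Their covariance was 0.265, against 0.0326 to 0.0546 in the simulations. It moved to 0.492 with a pseudocount of 0.1, against 0.0747 to 0.111 in simulations at that setting, and to 0.211 with no filter, against 0.0246 to 0.0374. The 3 Large White libraries cannot be split into groups of at least 2, so part of the excess in shared calls may come from these shared controls.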

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

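The tests of normalization, cell composition, developmental stage, shared controls and single libraries in this part were chosen after the results were seen, except the counts over other splits of the libraries and the test for immune cells in Wujin 1.

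Against Large White, 79 genes were called in opposite directions in Tibetan and in Wujin muscle and also differed between Tibetan and Wujin, 17 higher in Tibetan and 62 higher in Wujin. Direction here is that of the fitted change, whose median over all genes was -0.77 in Tibetan and -0.20 in Wujin. Such shifts favour lower calls, more so in Tibetan, and the 79 were not recounted after rescaling. Independent lists of the same sizes as both sets of calls would share 221 in opposite directions. Simulated unchanged groups shared 0, but they give almost no calls, so that count is no baseline. CKMT2, the mitochondrial creatine kinase of muscle, differed by 6.35 ± 0.20 (log2) between Tibetan and Wujin (limma, adjusted p = 5.44e-08). It was 5.54 above Large White in Tibetan and -0.82 from it in Wujin (adjusted p = 0.0447). The Wujin call ended under each of the 4 scalings, with a pseudocount of 0.1 (-0.89), with no expression filter or only the 6 libraries (both -0.82), and without Tibetan 1, 2 or 3, Wujin 1 or b, or Large White 1, 2 or 3, with fitted values of -0.82, -0.82 and -0.82, -0.77 and -0.68, and -0.79, -0.91 and -0.75. COX2, here the mitochondrially encoded cytochrome oxidase subunit, differed by 1.18 ± 0.15 between Tibetan and Wujin (adjusted p = 8.45e-05), with 0.48 ± 0.15 against Large White in Tibetan (adjusted p = 0.0132) and -0.70 ± 0.15 in Wujin (adjusted p = 0.0346). Its Tibetan value turned to -0.20 after quantile normalization, and its Tibetan call ended with equal totals (0.34), with no filter or a replicate block (both 0.48), and without Large White 2 (0.46) or 3 (0.43). Its Wujin call ended under median-ratio scaling (-0.47), with equal totals (-0.61), with no filter or only the 6 libraries (both -0.70), and without Tibetan 1 (-0.70), Wujin 1 (-0.59), Wujin a (-0.73) or Large White 1, 2 or 3 (-0.62, -0.72 and -0.76). In both genes the test of the difference is the comparison of Tibetan with Wujin.

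The Tibetan libraries lay apart from both other breeds. The authors' normalization alone is argued against as the whole cause only by the genes called lower in Tibetan than in Large White libraries. Of these 8280 genes, 4327 stayed called lower under median-ratio scaling, and the rest lost the call or, in 407 cases, changed direction. All 1703 higher genes stayed called, but this scaling raises Tibetan against Large White values, so they could not tell. The share of both directions together, 60.4%, therefore overstates how far the calls were tested. Fewer cells other than muscle in the Tibetan samples would alone raise every sarcomere list alike. As the whole cause this is argued against. The embryonic and neonatal sarcomere list lay at -2.91 or below relative to all genes in every Tibetan library, while the common sarcomere list lay between 2.20 and 2.34. The embryonic list holds 9 measured genes, of which MYH8 rose, and was not called before rescaling. Fewer such cells as a part of the cause stay open, as the extracellular matrix list lay between -2.63 and -2.46. The lists of such cells did not move alike, however. Cartilage, bone and tendon (-2.46 to -2.05) and neural and Schwann (-1.36 to -0.99) were also low in every Tibetan library. Endothelial and mural (0.17 to 0.53), macrophage and immune (0.35 to 0.97), erythroid (0.06 to 0.27) and adipogenesis (0.09 to 0.75) lay above all genes, and liver and visceral was mixed (-0.74 to 1.37). A later developmental stage of the Tibetan samples cannot be told apart from breed, because no gestational day is given per sample, and a difference between the breeds at the same stage stays open and untested. In the direction that more mature muscle would give, 51 of 54 members of the fast-fibre, cell cycle and embryonic sarcomere lists were called, or 94.4%. This share does not test stage, because the lists were chosen after they had moved this way, MYH8 was counted as higher, and 8280 of the 13106 genes were called lower anyway.

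The Wujin libraries lay between Large White and Tibetan on the first principal component, at -23.2, -46.6 and -49.7 against -69.3 to -61.7 for Large White and 104 to 105.5 for Tibetan libraries. Independent noise in the shared Large White libraries is argued against as the only cause. The covariance of both sets of fold changes was 0.265, against at most 0.0546 in unchanged groups simulated with a shared control group. With a pseudocount of 0.1 it was 0.492 against at most 0.111, and with no expression filter 0.211 against at most 0.0374. Wujin 1 alone is argued against too, as the covariance was 0.209 without it. The correlation of both sets was 0.419, below the lowest simulated value of 0.421. A shift common to the Large White libraries was not simulated and would raise the covariance too, so it stays open. A graded difference between the breeds and a graded difference in developmental stage stay open and untested.

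Interferon-response genes were high in Wujin 1 compared with the other Wujin libraries. For members of the MHC class I and interferon response list, the median difference from the mean of those libraries was 1.52 (log2). Of the 22 members, 20 were higher in Wujin 1. Tibetan libraries had high values too: relative to all genes and the Large White mean, the list's median was 1.53, 1.32 and 1.45 in Tibetan 1, 2 and 3. It was 1.83, 0.12 and 0.24 in Wujin 1, a and b. MX1 stood at 37.6 FPKM in Wujin 1 against 1.34 and 0.961 in Wujin a and b, OAS2 at 30.8 against 3.69 and 4.01, IRF9 at 42.0 against 7.64 and 8.40, and USP18 at 8.17 against 0.714 and 0.668. A shift of all genes in Wujin 1 is argued against, as the 13084 tested genes outside the list had a median of -0.22, with quartiles of -0.52 and 0.05, against quartiles of 0.63 and 1.98 in the list. More immune cells in Wujin 1 is argued against too, as the macrophage and immune list moved by -0.17, a ratio of -0.113 to the shift of the interferon list. A technical shift of only some genes stays open, and no other biological explanation was tested, because the design gives no group that would set this library apart.

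Other splits of the libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05: the real split gave 9983 calls for Tibetan and Large White against at most 0 in the others, 855 against 4 for Wujin and Large White, and 8871 against 2 for Tibetan and Wujin. For the mean of Tibetan and Wujin against Large White, chance could not be excluded, since 5 of 100 splits, the real one included, gave at least its 8643 calls, with 9387 as the highest other. The 4 others were all those that set the 3 Tibetan libraries alone against the remaining 6, which points to a structure of the samples. For any difference among the breeds, only the real split of the 100 reached its 10173 calls, and the highest other gave 9027. Chance between animals cannot be excluded by this, because the labels do not say that libraries of a breed came from separate animals. The 3 other splits that kept the Tibetan libraries together gave up to 9027 and the rest at most 3, so this count mainly reflects the Tibetan libraries and says little about Wujin against Large White.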

How the results depend on the processing

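The 2 settings added after the data were seen, with zeros beside high values as missing and without Tibetan 2 and Wujin 1, are the only ones not planned. With a value for each alternative, the named genes kept their direction and their side of the threshold in 1945 of 1975 values for Tibetan minus Large White, 916 of 1140 for Wujin minus Large White, 519 of 527 for Tibetan minus Wujin and 210 of 210 for the mean of both breeds. In Wujin minus Large White the other 224 values lost the call. The lists kept theirs in 641 of 724, 661 of 695 and 627 of 695 values of the 3 pairwise comparisons. Values that were not called and only changed sign, 84 in all, are counted as kept. Depth in reads is unknown, so the counting error of genes with low FPKM cannot be given. The cause of each change was not tested, unless the setting itself removes genes or libraries.

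The reported calls were 9983 for Tibetan minus Large White, 855 for Wujin minus Large White, 8871 for Tibetan minus Wujin, 8643 for the mean and 10173 for any difference, with an overlap of 693. With only genes of at least 5 FPKM, fewer genes were tested, and the calls were 5533, 402, 5181, 4814 and 5717 in that order. With an absolute log2 fold change of at least 1 they were 6149, 227, 4788 and 2918. The Wujin minus Large White calls moved to 270 with a pseudocount of 0.1, 1831 with 5, 412 under median-ratio scaling, 453 with equal totals without the 50 highest genes, and 280 with only the 6 libraries of these breeds. The overlap of both comparisons with Large White moved to 214 with a pseudocount of 0.1 and 292 under median-ratio scaling. For the calls, other planned settings, libraries left out aside, stayed within 1.5 times. The overlap was otherwise counted only with no filter, where it was 694, after quantile normalization, where it was 590, and with libraries left out. With zeros as missing, the added setting gave 10002, 900, 8888, 8659 and 10185 calls, and without Tibetan 2 and Wujin 1 it gave 10362, 957, 9498, 9014 and 10383.

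With 1 library left out, calls ranged from 9240 to 10410 for Tibetan minus Large White, 66 to 1633 for Wujin minus Large White, 8024 to 9578 for Tibetan minus Wujin, 7201 to 8773 for the mean, 9342 to 10421 for any difference, and 54 to 1366 for the overlap. The lowest of the wide ranges came without Large White 3 and the highest without Wujin b. A library left out removes residual degrees of freedom for every comparison. Lists called ranged from 16 to 21, 5 to 10, 19 to 23 and 13 to 17, with 5 for Wujin minus Large White without Wujin 1.

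With an estimated correlation, 0 lists were called in each comparison, against 20, 8, 22 and 17 with the preset one and 21, 3, 23 and 20 with fry. At an unadjusted p under 0.05, an estimated correlation gave 7, 1, 8 and 7 lists. Of the lists called for Tibetan minus Large White, those of fast fibres, common sarcomere, cell cycle, extracellular matrix, TGF-beta, fatty acid oxidation, nuclear oxidative phosphorylation, tricarboxylic acid cycle, glycolysis, proteasome and stress lost the call with an estimated correlation alone, and the 9 others also under at least 1 more setting. For Wujin minus Large White, 5 were called with at least 5 FPKM. fry tests the fitted changes without comparing them with other genes. Among the lists called by camera or by fry, some had another direction under fry. For Tibetan minus Large White these were growth factor signalling (adjusted p = 0.00137), adipogenesis (0.726), hypoxia (0.349), endothelial and mural (0.00137) and pig trait genes (0.00075). With the direction unchanged, fry ended the calls of slow fibres (0.0568), the mitochondrial genome (0.170), macrophage and immune (0.811) and interferon response (0.266). It called embryonic sarcomere (2.54e-07), myogenic regulators (8.73e-07), Wnt (4.48e-06) and neural genes (2.54e-07), which camera had not. For Wujin minus Large White the list with another direction under fry was neural and Schwann (0.0388). Here fry ended the calls of common sarcomere (0.340), nuclear oxidative phosphorylation (0.834), the mitochondrial genome (0.0757), glycolysis (0.349), interferon response (0.468) and endothelial and mural (0.613). For Tibetan minus Wujin the lists with another direction under fry were growth factor signalling (0.0027), endothelial and mural (0.000861), liver and visceral (0.789) and pig trait genes (0.0386). There fry ended the calls of hypoxia (0.682), macrophage and immune (0.394) and interferon response (0.789), and it called embryonic sarcomere (2.04e-07) and neural genes (9.37e-07). The mitochondrial genome list of Tibetan minus Large White reversed with quantile normalization (adjusted p = 0.953), as did COX1 (-0.061) and COX2 (-0.20), and MYOD1 reversed with median-ratio scaling (0.060).

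Tibetan and Large White share replicate numbers, but same-numbered libraries deviated together with correlations of 0.013, -0.0226 and -0.0760, and not every library correlated best with its own number, so the numbers do not pair them. With the replicate block the calls were 10064, against 10253 in the same 6 libraries without it. No paired analysis was possible because of the shared header for the comparisons that include Wujin.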

Other observations

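All values in this part were looked up after the results were seen, and no test of an explanation is reported here.

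Levels of GAPDH, FOS and HBB also differed between Tibetan and the other breeds. GAPDH, often used as a reference gene, stood at 40872 ± 3141 FPKM in Tibetan (SD, n = 3), 4236 ± 421 in Wujin and 2814 ± 379.9 in Large White libraries. FOS, an immediate early gene, stood at 210.4 ± 114 FPKM in Tibetan against 5.81 and 5.26 in Wujin and Large White libraries (limma, fitted log2 change from Large White 4.95 ± 0.34, adjusted p = 1.92e-06). HBB, beta-globin, stood at 191, 573 and 145 FPKM in Tibetan 1, 2 and 3, at 1459, 3809 and 1791 in Wujin 1, a and b, and at 3717, 1910.4 and 2423 in Large White 1, 2 and 3 (fitted change of Tibetan from Large White -3.35 ± 0.53, adjusted p = 0.000338).

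Large White 2 and 3 carried transcripts of liver proteins, and Tibetan 1 carried some of them. AHSG, fetuin, stood at 30.0 and 43.0 FPKM in these and at 1.10 in Large White 1, TF, transferrin, at 11.1 and 15.0 against 0.781, and AFP, alpha-fetoprotein, at 6.23 and 8.75 against 0.205. AHSG was at most 0.261 FPKM in the Wujin libraries and 7.72, 1.14 and 0.103 in Tibetan 1, 2 and 3. TF was at most 0.421 FPKM in the Wujin libraries and 7.41, 2.37 and 0.620 in Tibetan 1, 2 and 3, while AFP was at most 0.0295 in Tibetan libraries. TNNC1, slow and cardiac troponin C, stood at 8645 FPKM in Tibetan 2 against 1663 and 1615 in Tibetan 1 and 3.

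Some zeros stand beside very high values. There were 39 zeros in 15 genes where another library of the same breed had at least 100 FPKM. ACTA1, skeletal alpha-actin, was listed at 0 in Tibetan 2, beside 37424 and 41829 FPKM in Tibetan 1 and 3 and 3208 to 7148 in the other 6 libraries. The entry ENSSSCG00000019894 was listed at 52818 FPKM in Tibetan 3, 51249 in Large White 2 and 0 in the other 7 libraries. Since skeletal muscle is built on this actin, such a 0 was read as a listed value only. Another entry without a symbol, ENSSSCG00000018006, stood at 5972, 3229 and 8094 FPKM in Tibetan 1, 2 and 3, at 4.62, 14.7 and 16.6 in Wujin 1, a and b, and at 12.7, 6.92 and 15.3 in Large White 1, 2 and 3.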
